A study of Mus musculus with 4 samples.

How the data were processed

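Messenger RNA was sequenced from flow-sorted macrophages of the liver of C57BL6J mice aged 8 weeks, with the Tecan universal plus mRNA-seq kit, per the labels. The design has 4 libraries: 3 of Cxcr4+ macrophages taken 72 h after an intraperitoneal injection of 300 mg/kg acetaminophen (APAP), and 1 of control macrophages. The labels name the Cxcr4+ sort only for the APAP group and do not describe the gate used for the control, so the effects of APAP and of the sort cannot be separated here. The labels also do not say whether the 3 APAP libraries came from separate animals, so p-values measure the spread between these samples, which may be technical. The columns of the APAP group carry no replicate number and were numbered 1 to 3 in the order in which they stand in the table.

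The deposited values are read counts per Ensembl gene, whole numbers and not normalized. Per the submitters' processing notes, HISAT2 and Subread were used with genome build mm39. The versions and roles of these tools, the annotation, the strand setting and the handling of reads shared between genes are not given in the sources used here. Reads of overlapping, antisense and near-identical genes, such as the immunoglobulin segments, may therefore be split or shared in a way that the counts do not show. The table held 29247 gene IDs, of which 28926 (98.9%) were matched to a symbol; the other 321 IDs took 0.141% to 0.147% of the counts in the APAP libraries and 0.562% in the control. A single one of these IDs took 0.0797% to 0.0881% in the APAP libraries and 0.509% in the control, so most of that difference comes from it. Names were taken from gene tables for the mouse genome, and no coordinates are printed, because the annotation at hand belongs to another build.

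Total counts were 48282283, 52043418 and 56702837 in the APAP libraries and 49950909 in the control. For genes with 0 counts in the control, the fold is a lower bound against a floor of 3 counts in that library, and this bound covers counting error only. Values in CPM, counts scaled to a common library size, use totals scaled by trimmed mean of M-values (TMM) factors, which were 1.04, 1.03 and 1.03 for the APAP libraries and 0.90 for the control.

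Genes were tested with edgeR 4.0.16 in R 4.3.3: the default filterByExpr filter (minimum count 10, minimum total 15) kept 18715 genes, and the quasi-likelihood F test compared the groups without covariates. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. With a single control library, the spread comes from the 3 APAP libraries alone (2 residual degrees of freedom, moderated with 3.80 prior degrees of freedom), and the control is assumed to vary like them. The common biological coefficient of variation was 0.162. The test was also run on simulated counts for 18715 genes. It recovered 56.7% of 67 genes changed 2-fold, 97.0% of 67 changed 4-fold and 100% of 66 changed 8-fold, and called 19 of 17800 unchanged genes. The simulated control was drawn with the same spread as the APAP libraries, so these rates leave out errors from a deviating control library.

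Gene lists were tested against the other genes tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 37 lists with at least 5 measured members. The lists covered macrophage programmes, metabolic and stress pathways, markers of the other cell types that a liver macrophage gate could hold, and an immediate early list as a quality measure. With a simulated change in the lysosome list, camera called that list and 2 others. The changed list had an adjusted p of 0.063 with an estimated correlation and of 0.0379 with fry, another list test. The simulated genes were drawn independently of each other, while the estimated correlation in the data ran from -0.04 to 0.98 over the lists. The simulation therefore leaves out false calls of lists whose members move together.

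The groups, the tests, the lists, the alternatives and the rule for the genes to be named were chosen before the data were examined. The rule took the 10 largest rises and the 10 largest falls among called genes with an average log2 CPM of at least 5, all 3 APAP libraries on the same side of the control and a symbol that is not a predicted or clone name. It also took up to 4 members per list with the smallest p-values, the defining gene of a list where that is its first entry, and Cxcr4, Xist and Ddx3y. Genes named outside the rule are said to have been picked after their values were seen.

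The alternatives were DESeq2 (1.42.0) size factors, upper-quartile factors, no count filter, a filter of 5 CPM in at least 1 library, leaving out each APAP library, leaving out mitochondrial and ribosomal protein genes, leaving out the hepatocyte list, the DESeq2 Wald test, limma-voom, a test against a log2 fold change of 1 (glmTreat), camera with an estimated correlation, and fry. A correction of the fold changes for their trend over transcript length and GC content was added after the data had been seen. It used the median length and GC content of the GENCODE vM21 transcripts of each gene, which covered 99.6% of the genes tested. No sample and no column of the table was left out.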

Results

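Gene expression was measured by RNA sequencing in flow-sorted liver macrophages of C57BL6J mice. The labels define a single contrast. It sets 3 libraries of Cxcr4+ macrophages, taken 72 h after acetaminophen (APAP, 300 mg/kg), against 1 library of control macrophages. APAP is a drug that kills hepatocytes at high doses. Total counts were 48282283, 52043418 and 56702837 in the APAP libraries and 49950909 in the control. The APAP libraries resembled each other (Pearson correlation of log2 CPM across genes 0.984 to 0.987) more than they resembled the control (0.923 to 0.932). Read counts differed between every pair of libraries by more than sampling noise, so no library was a copy of another. Chi-square per degree of freedom was 16.5 to 56.7 within the APAP group and 356 to 405 with the control. Between 23376 and 23880 genes had reads in the APAP libraries and 18793 in the control, and the numbers at equal depth were 23376 to 23776 and 18783.

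Cxcr4, the sort marker of the APAP group, stood at 84.5, 132 and 101 CPM in the APAP libraries and at 41.3 CPM in the control, a log2 fold change of 1.36 (SE 0.26, adjusted p = 0.00978). This checks the labels and is not an independent finding. Xist had 0 to 4 counts in every library, and the Y-linked Ddx3y was at 83.3 to 102 CPM in the APAP libraries and 61.8 CPM in the control.

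Most of the monocyte and lipid-associated macrophage genes tested were higher in APAP Cxcr4+ macrophages, and most genes that mark Kupffer cells, the resident macrophages of the liver, were lower. Gpnmb, a glycoprotein of lipid-laden and scar-associated macrophages, rose from 1.60 CPM in the control to 3258 ± 1448 CPM (SD, n = 3), and the chemokine receptor Ccr2, which marks monocytes recruited from blood, rose from 10.8 to 262 ± 35.5 CPM. The Kupffer cell lectin Clec4f fell from 13079.6 to 3846 ± 965 CPM and the phosphatidylserine receptor Timd4 from 945 to 291 ± 43.5 CPM. In the same libraries, 10 of 14 MHC class II genes, the complement component C1q and interleukin 1 beta were lower, and all 18 B cell markers were higher.

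Of the 16 measured Kupffer cell identity genes, 13 fell and 0 rose (median log2 fold change -1.16, camera adjusted p = 1.3e-08). The list had an adjusted p of 0.65 with an estimated correlation, and the counts adjusted over the list alone were the same. Without the second APAP library 10 fell, and without the third 14 fell and 1 rose. Log2 fold changes were -2.46 (SE 0.26) for the ficolin Fcna, -2.11 (SE 0.21) for the folate receptor Folr2, -1.77 (SE 0.26) for Clec4f, -1.77 (SE 0.15) for Pcolce2 and -1.70 (SE 0.16) for Timd4, with adjusted p between 0.00127 and 0.00465. Marco at 0.62, Cd163 at -0.50 and Spic at -0.18, picked after their values were seen, did not pass the test (adjusted p = 0.109, 0.413 and 0.161).

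Of 18 measured monocyte and early monocyte-derived macrophage genes, 13 rose and 1 fell, the same as when adjusted over the list alone (median 2.69, camera adjusted p = 1.03e-09; adjusted p = 0.65 with an estimated correlation). The fractalkine receptor Cx3cr1 rose by 4.79 on the log2 scale (SE 0.29), Ccr2 by 4.60 (SE 0.22), the coagulation factor F13a1 by 5.36 (SE 0.31) and Ly6c2, which marks inflammatory monocytes, by 2.42 (SE 0.46, adjusted p = 0.00988). Chil3, a chitinase-like protein, had 0 counts in the control and 47.3 ± 13.2 CPM in the APAP libraries, at least 708-fold higher. The member that fell was Plac8 (log2 fold change -1.76), picked after its value was seen, and 2 fell without the first APAP library.

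Among 18 lipid- and scar-associated macrophage genes, 12 rose and 0 fell, and 13 rose when adjusted over the list alone (median 2.31, camera adjusted p = 1.52e-08; adjusted p = 0.65 with an estimated correlation). The summed CPM of the list was not higher (54378, 51342 and 54321 in the APAP libraries and 54744 in the control). Gpnmb rose by 10.99 (SE 0.83), the tetraspanin Cd63 by 5.16 (SE 0.39), the lipid receptor Trem2 by 2.34 (SE 0.13) and the integrin Itgax by 2.28 (SE 0.13). The osteopontin gene Spp1 rose by 7.59 (SE 1.57, adjusted p = 0.0129), at 122 CPM in the first APAP library, 30.1 and 29.3 CPM in the others and 0.312 CPM in the control. Without the first APAP library the Spp1 value was 6.56, and limma-voom gave it an adjusted p of 0.189.

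**Figure D1:**
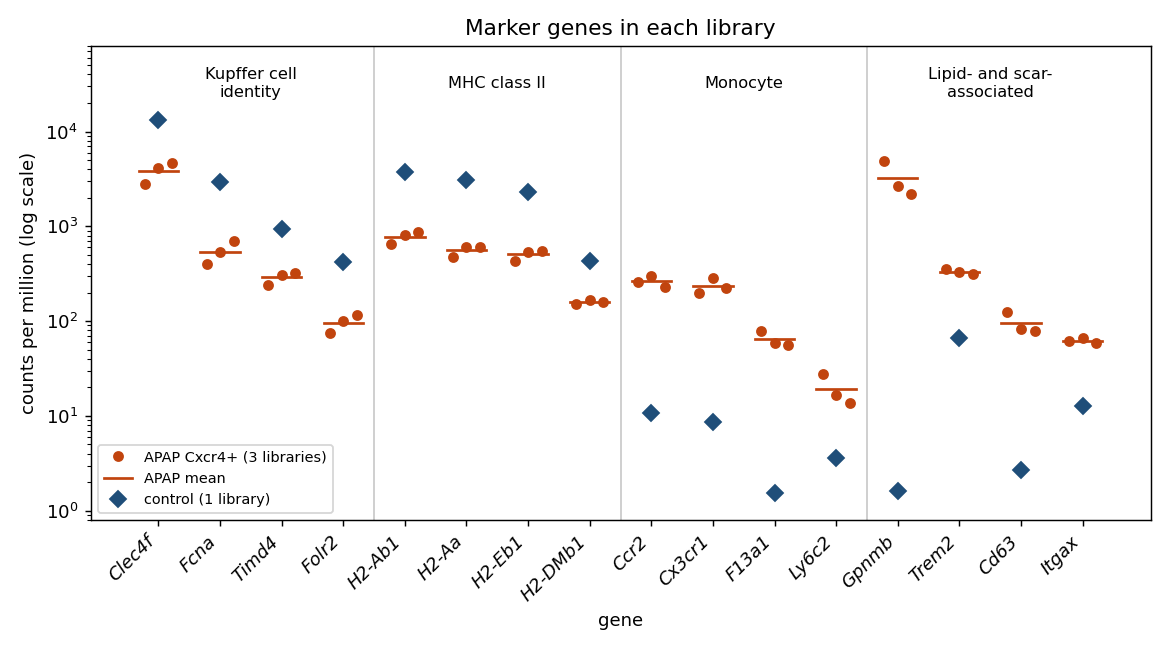
Expression in CPM (log axis) of 16 marker genes, with a point for each of the 3 APAP Cxcr4+ libraries, a line at their mean and a diamond for the 1 control library. Clec4f stands at 13079.6 CPM in the control and 3846 CPM on average after APAP, and Gpnmb at 1.60 and 3258 CPM.

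Most antigen presentation genes were lower in APAP Cxcr4+ macrophages. Of 14 measured MHC class II genes, 10 fell and 3 rose, the same as when adjusted over the list alone (median -1.35, camera adjusted p = 6.52e-09; adjusted p = 0.65 with an estimated correlation). H2-Aa fell by 2.47 (SE 0.16), H2-Ab1 by 2.28 (SE 0.17), H2-Eb1 by 2.18 (SE 0.15) and H2-DMb1, a chaperone of peptide loading, by 1.43 (SE 0.09). The 3 that rose, picked after their values were seen, were the class II transactivator Ciita (1.13), H2-Oa (3.32) and H2-Ob (1.86). The product of H2-Oa and H2-Ob modulates peptide loading and is known mainly from B cells and dendritic cells.

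Of 20 complement and Fc receptor genes, 14 fell and 3 rose, and 15 fell when adjusted over the list alone (median -1.01, camera adjusted p = 1.17e-07; adjusted p = 0.65 with an estimated correlation). The complement genes C4b and C1qa fell by 2.58 (SE 0.10) and 2.18 (SE 0.21), and the Fc receptor genes Fcgr4 and Fcer1g by 1.60 (SE 0.12) and 1.15 (SE 0.09). Itgax, at 2.28, and the inhibitory receptor Fcgr2b, at 1.52, were among the 3 that rose.

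Of 21 inflammatory cytokine and chemokine genes, 9 fell and 3 rose, and 10 fell when adjusted over the list alone (median -0.79, camera adjusted p = 0.00991; adjusted p = 0.65 with an estimated correlation). Without the first APAP library 11 of 20 measured genes fell, without the second 6 of 20 and without the third 10 of 21. Il1b fell from 617 to 87.7 ± 8.7 CPM (log2 fold change -2.81, SE 0.12), Il1a fell by 0.79 (SE 0.14) and the receptor antagonist Il1rn by 0.83 (SE 0.11). Oncostatin M (Osm) rose by 3.45 (SE 0.30) and Ccl3 by 1.43 (SE 0.19). Among 24 type I interferon response genes, 10 fell and 2 rose (11 and 3 adjusted over the list alone; median -0.28, camera adjusted p = 0.00346; adjusted p = 0.78 with an estimated correlation). Without the first APAP library 5 rose, and without the second or the third 1 rose. The transcription factor Irf7 fell by 1.72 (SE 0.14) and the ubiquitin-like Isg15 by 1.12 (SE 0.12).

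Receptors that guide leukocyte migration went both ways. Of 22 measured chemotactic receptor genes, 12 rose and 3 fell, the same as when adjusted over the list alone (median 0.75, camera adjusted p = 0.00107; adjusted p = 0.65 with an estimated correlation). Ccr1 rose by 3.92 (SE 0.39) and the platelet-activating factor receptor Ptafr by 3.84 (SE 0.26), and the formyl peptide receptor Fpr2 fell by 2.33 (SE 0.13). The 12 that rose included Cxcr5 (3.36) and Ccr7 (3.86), known from lymphocytes and dendritic cells and picked after their values were seen. Cxcr2, known from neutrophils, rose by 6.71 (adjusted p = 0.0201, and 0.289 with limma-voom).

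Mitochondrial respiratory chain genes were lower as a group: of 34 oxidative phosphorylation genes, 28 fell and 0 rose, and 30 fell when adjusted over the list alone (median -0.81, camera adjusted p = 4.57e-13; adjusted p = 0.65 with an estimated correlation). Without the first APAP library 31 fell, without the second 22 and without the third 27. The cytochrome oxidase subunits Cox5a and Cox7a2 fell by 1.47 (SE 0.08) and 1.37 (SE 0.12), and the complex I subunits Ndufa2 and Ndufb9 by 1.36 (SE 0.11) and 1.12 (SE 0.11). In these libraries, fold changes also followed transcript length. Spearman's rho across 9280 genes, which are not independent replicates, was 0.468, against -0.098 to -0.021 between pairs of APAP libraries. After a correction for length and GC content, chosen after the data were seen, 20 oxidative phosphorylation genes fell and 1 rose (median -0.46). Mitochondrial transcripts took 1.99% to 2.33% of counts in the APAP libraries and 2.91% in the control, and ribosomal protein genes 2.29% to 2.36% and 3.12%.

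**Figure D2:**
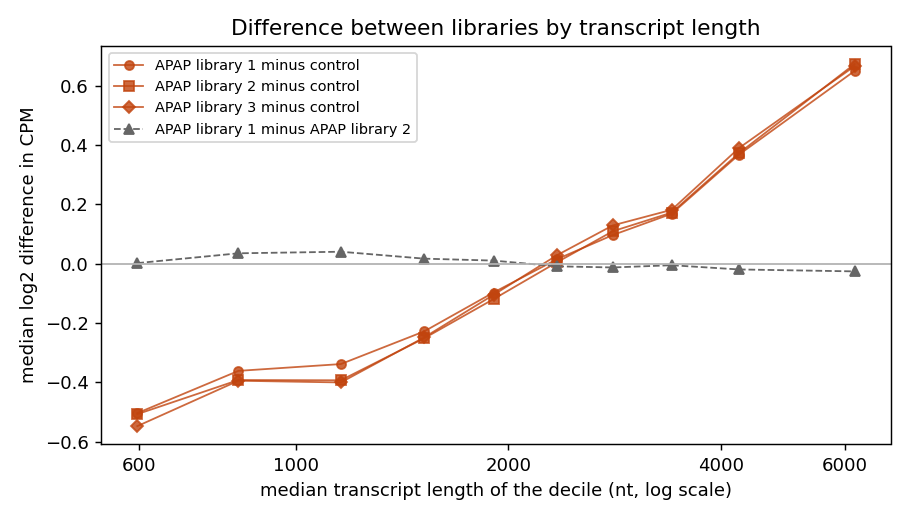
Median log2 difference in CPM between libraries (vertical axis) for deciles of genes by transcript length in nt (log axis), for each APAP library minus the control and for the first minus the second APAP library. Fold changes against the control run from a median of -0.51 in the shortest decile (median 596 nt) to 0.66 in the longest (median 6193 nt).

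Genes of the unfolded protein response fell in 6 of 21 cases and rose in 1 (3 and 1 adjusted over the list alone; median -0.41, camera adjusted p = 0.0331; adjusted p = 0.86 with an estimated correlation). Xbp1 fell by 0.69 (SE 0.08) and Manf by 1.31 (SE 0.17), and Atf3 rose by 1.84 (SE 0.25). The call was lost without the second or the third APAP library (adjusted p = 0.0502 and 0.111) and with a stricter count filter (0.0839), and 15 genes fell without the first APAP library and 3 without the second.

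Markers of lymphocytes moved with the APAP group, in cells labelled as macrophages. Of 18 B and plasma cell genes, 18 rose, adjusted over all genes or over the list alone (median 3.46, camera adjusted p = 4.57e-13; adjusted p = 0.65 with an estimated correlation). Immunoglobulin M heavy chain (Ighm) rose from 23.2 to 181 ± 34.3 CPM and the kappa constant region Igkc from 13.4 to 147 ± 28.0 CPM. The complement receptor Cr2, with 0 counts in the control, was at least 137-fold higher. Of 20 T cell genes, 17 rose and 0 fell, and 19 rose when adjusted over the list alone (median 1.31, camera adjusted p = 6.98e-05; adjusted p = 0.77 with an estimated correlation). Il7r rose by 2.19 (SE 0.20), Lck by 1.55 (SE 0.19) and Tcf7 by 2.40 (SE 0.32), while Cd3d, at 0.58, did not pass (adjusted p = 0.056), except after the length and GC correction (0.82, adjusted p = 0.0237). Without the second APAP library 11 T cell genes rose.

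Of 16 NK cell and ILC1 genes, 10 rose and 1 fell, and 11 rose when adjusted over the list alone (median 1.56, camera adjusted p = 0.00583; adjusted p = 0.65 with an estimated correlation). Without the second APAP library 6 rose, and the list's call was lost with a stricter count filter (adjusted p = 0.208). Klrd1 rose from 0.156 to 6.05 ± 1.47 CPM and Ncr1 from 0.356 to 2.86 ± 0.26 CPM. Of 12 plasmacytoid dendritic cell genes, 9 rose and 2 fell, and 10 rose when adjusted over the list alone (median 3.55, camera adjusted p = 2.68e-06; adjusted p = 0.65 with an estimated correlation). Without the second APAP library 1 fell. The summed CPM of that list was lower after APAP (482, 521 and 547 against 644), because the 2 members that fell, Bst2 (-1.26) and Lair1 (-0.55), picked after their values were seen, were the most abundant in the control. Siglech, with 0 counts in the control and 18.2 ± 5.15 CPM in the APAP libraries, was at least 273-fold higher, and the transcription factors Runx2 and Spib rose by 5.37 (SE 0.24) and 3.67 (SE 0.24).

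Neutrophil markers rose in 6 of 15 cases and fell in 0, also when adjusted over the list alone (median 2.48, or 2.46 with members at 0 in the control at their lower bound; camera adjusted p = 0.0331; adjusted p = 0.77 with an estimated correlation). The collagenase Mmp8 had 6 counts in the control and 26.9 ± 14.1 CPM in the APAP libraries (adjusted p = 0.00326, and 0.0925 with limma-voom), and S100a8, at a log2 fold change of 2.45, did not pass (adjusted p = 0.0809). Its value was lower without the first APAP library, at 1.77 (adjusted p = 0.038), and 2.87 without the third (adjusted p = 0.000511). Without the third APAP library 11 neutrophil genes rose and 1 fell, and 1 fell without the first, where the median was 1.85. The neutrophil list's call was lost with a stricter count filter (adjusted p = 0.0866).

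Most hepatocyte transcripts tested were lower in the APAP libraries, in cells labelled as macrophages, and the source of this fall was not tested. Of 30 measured hepatocyte genes, 21 fell and 0 rose, and 23 fell when adjusted over the list alone (median -1.55, camera adjusted p = 3.63e-09; adjusted p = 0.77 with an estimated correlation). Without the first APAP library 22 fell (median -1.36), without the second 16 (median -1.26) and without the third 29 (median -2.07). The summed CPM of the list was 1678, 1936 and 2734 in the APAP libraries and 4474 in the control. Albumin (Alb) fell from 492 to 222 ± 46.3 CPM, the fibrinogen chains Fgb and Fga by 2.35 (SE 0.27) and 2.22 (SE 0.29), and the apolipoprotein Apoa1 by 2.24 (SE 0.29). All 30 of these genes stood at 1 CPM or more in the control, as did 12 of 18 B cell, 20 of 20 T cell, 9 of 16 NK cell, 7 of 12 plasmacytoid dendritic cell and 6 of 15 neutrophil genes. Other lists held 1 of the hepatocyte, 0 of the B cell, 0 of the T cell, 1 of the NK cell, 1 of the plasmacytoid dendritic cell and 3 of the neutrophil genes. They held 5 of 16 Kupffer cell, 6 of 18 monocyte, 5 of 18 lipid-associated, 9 of 20 complement and 6 of 22 chemotactic receptor genes. The overlap was 0 for MHC class II and oxidative phosphorylation, 1 for interferon and unfolded protein response and 2 for cytokine genes. Lists that share genes, such as Ccr2 and Cx3cr1 in the monocyte and chemotactic receptor lists, are not separate results.

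Across all genes, 8295 of 18715 tested passed the edgeR quasi-likelihood test at an adjusted p of 0.05, with 4758 higher and 3537 lower in APAP Cxcr4+ macrophages. Of these, 2850 were at least 2-fold higher and 1382 at least 2-fold lower. Besides Gpnmb, Chil3, Spp1, F13a1 and Cd63, the 10 largest rises of abundant genes included the motor protein Myo5a (7.23, SE 0.32), the surface receptor Cd93 (5.92, SE 0.31), the metalloprotease Adam8 (5.60, SE 0.48) and the integrin Itga6 (5.16, SE 0.23). The 10 largest falls were led by the B cell chemoattractant Cxcl13 (-4.15, SE 0.35) and langerin (Cd207, -3.10, SE 0.33), with Ms4a8a (-2.76), the guanylate-binding protein Gbp2b (-2.73) and Wfdc17 (-2.50). The others were the serpin Serpina3k (-2.68), known from hepatocytes, and Il1b, C4b, H2-Aa and Fcna. The control lay outside the range of the APAP libraries for 84.8% of the genes tested, where chance gives 50%. The count rests on 1 control library, and it was 5001 without the second APAP library and 1379 when tested against a 2-fold change.

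**Figure D3:**
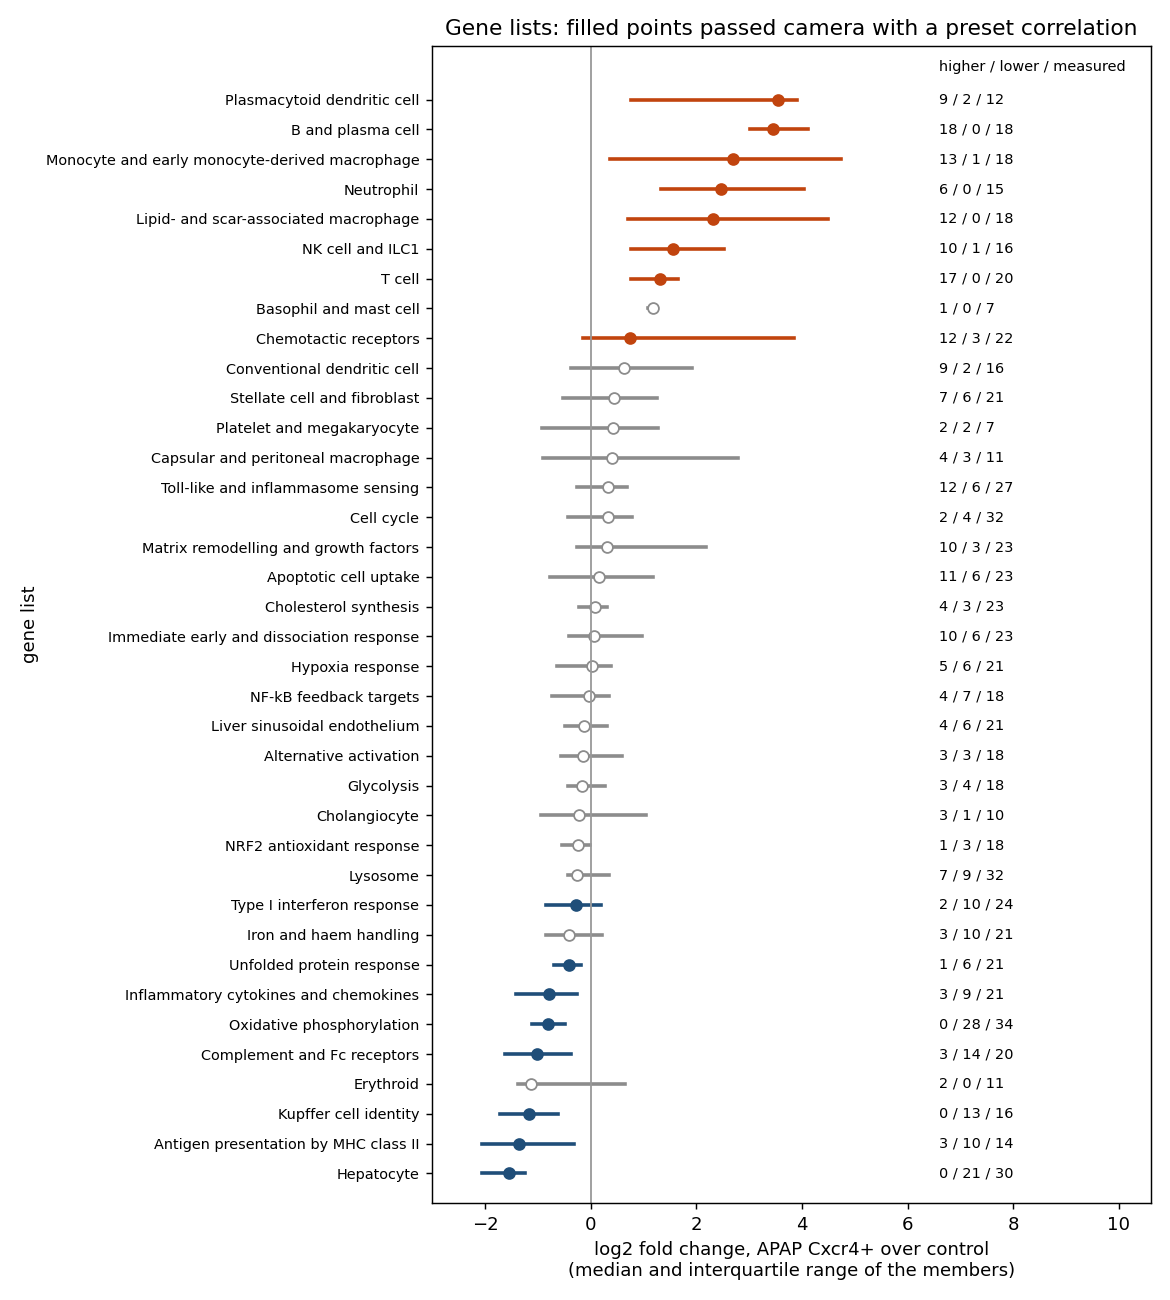
Median and interquartile range of the log2 fold change, APAP Cxcr4+ over control, of the measured members of 37 gene lists, with members at 0 counts in the control at their lower bound. Filled points passed camera at an adjusted p of 0.05 (8 up in red, 8 down in blue), and the numbers are the members higher, lower and measured. The medians run from -1.55 (hepatocyte) to 3.55 (plasmacytoid dendritic cell).

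The other 21 lists did not pass camera, although single members did. Iron and haem handling had 3 genes higher and 10 lower of 21 (5 and 10 adjusted over the list alone; adjusted p = 0.0559, 0.0122 with no count filter and 0.00649 without the first APAP library), with the biliverdin reductase Blvrb at -0.92 and the receptor Lrp1 at 1.25. Conventional dendritic cell markers had 9 higher and 2 lower of 16 (9 and 4 over the list alone; adjusted p = 0.0676, and 0.0275 and 0.0373 without the first and the second APAP library), with Cd209a at 4.66, Flt3 at 3.36 and Batf3 at -1.28. The lysosome list had 7 higher and 9 lower of 32 (9 and 13 over the list alone; adjusted p = 0.347). The NRF2 list had 1 higher and 3 lower of 18 (0 and 2 over the list alone; adjusted p = 0.176, and 0.00567 without the first APAP library), and NF-kB feedback targets 4 higher and 7 lower of 18 (5 and 7 over the list alone; adjusted p = 0.367). Glycolysis had 3 higher and 4 lower of 18 (adjusted p = 0.367) and hypoxia 5 higher and 6 lower of 21 (adjusted p = 0.616), both with the same counts over the list alone. Cholesterol synthesis had 4 higher and 3 lower of 23 (2 and 2 over the list alone; adjusted p = 0.934). Alternative activation had 3 higher and 3 lower of 18 (3 and 2 over the list alone; adjusted p = 0.934), with arginase Arg1 at -1.08 (adjusted p = 0.18, and -1.60 with an adjusted p of 0.00419 without the third APAP library). Several of these counts moved when 1 library was left out. Without the second APAP library, the genes higher and lower were 2 and 1 for the lysosome list, 3 and 5 for iron handling, 6 and 1 for conventional dendritic cells, 0 and 2 for NRF2 and 2 and 6 for NF-kB targets. They were 1 and 1 for glycolysis, 0 and 1 for cholesterol synthesis and 2 and 1 for alternative activation. Without the first they were 10 and 15 for the lysosome list, 5 and 12 for iron handling, 9 and 4 for conventional dendritic cells, 2 and 9 for NRF2 and 3 and 7 for glycolysis. Without the third they were 5 and 10 for iron handling and 2 and 4 for NRF2.

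Cell cycle genes had 2 higher and 4 lower of 32, and 0 and 2 over the list alone. The list's adjusted p was 0.616, and 0.0275 without the first APAP library, with the median at -0.11. Its summed CPM was 1449, 791 and 665 in the APAP libraries and 971 in the control. The 2 higher were Cenpf at 2.80, which did not pass with limma-voom, and Mki67 at 1.74 (adjusted p = 0.0448). For Mki67 it was 0.0702 without the second APAP library, 0.0756 with the DESeq2 Wald test and 0.133 after the length and GC correction. Among the 4 lower, Mcm3 fell from 89.3 to 44.6 ± 7.07 CPM and Tk1 stood at -1.35. Pcna, at -0.69, did not pass without the second APAP library. The cell cycle genes higher and lower were 5 and 14 without the first APAP library, 1 and 2 without the second and 11 and 7 without the third. Among markers of other liver and blood cells, the sinusoidal endothelium list had 4 higher and 6 lower of 21 (adjusted p = 0.428). After the length and GC correction it had 2 higher and 9 lower and passed as lower (median -0.41, adjusted p = 0.00535). Stellate cells and fibroblasts had 7 higher and 6 lower of 21 (adjusted p = 0.715), and capsular and peritoneal macrophages 4 higher and 3 lower of 11 (adjusted p = 0.666). Cholangiocytes had 3 higher and 1 lower of 10, and 0 of either over the list alone (adjusted p = 0.805). Erythroid genes had 2 higher and 0 lower of 11 (adjusted p = 0.703, and 9.4e-06 without the second APAP library, with the median at -2.27). Platelets had 2 higher and 2 lower of 7 (adjusted p = 0.939), and basophils and mast cells 1 higher and 0 lower of 7 (adjusted p = 0.364). Except for cholangiocytes these marker counts were the same over the list alone. Without the second APAP library they were 4 and 3 for the endothelium, 0 and 1 for cholangiocytes and 1 and 4 for erythroid genes. Basophils and mast cells had 3 and 0 without the first and 2 and 0 without the third, and cholangiocytes 1 and 2 without the third. The median and the camera direction differed in sign for hypoxia (median 0.02, tested as lower), cell cycle (0.32, lower) and cholesterol synthesis (0.08, lower). The mean and the median differed in sign for the sinusoidal endothelium (mean 0.22, median -0.12), erythroid (1.05 and -1.12), cholangiocyte (0.55 and -0.21) and alternative activation (0.65 and -0.15) lists.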

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

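The correction for transcript length and GC content was chosen after the data were seen, and the other alternatives here were planned. The main count of 8295 genes (4758 higher, 3537 lower) moved by less than 1.5 times under DESeq2 size factors (8292), upper-quartile factors (8347) and no count filter (8255). The same held without mitochondrial and ribosomal protein genes (8202), without the hepatocyte list (8325), with the DESeq2 Wald test (7996), with limma-voom (7778) and after the length and GC correction (7081, of which 5865 were shared and 25 had the opposite sign). A stricter filter tested 10959 genes and called 3097 higher. Against a 2-fold change, 1379 were called, 1099 higher and 280 lower, so 79.7% were higher in place of 57.4%. Leaving out each APAP library gave 5001 to 9380 genes, 2979 to 5195 higher and 2022 to 4185 lower, with the lowest values without the second library. No paired analysis was possible because there is only 1 control library and the columns carry no replicate numbers.

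Of 37 lists, 16 passed camera, with 13 to 21 under the other filters, factors, left-out libraries and corrections. With an estimated correlation 0 passed (smallest adjusted p = 0.653) and with fry 0 passed (smallest 0.0972), with the medians unchanged. The lists kept their counts of single genes under both, since those come from the gene test. The endothelium and matrix remodelling lists passed after the length and GC correction (adjusted p = 0.00535 and 0.0421), 5 further lists without the first APAP library, 3 without the second and 1, matrix remodelling, without the third. That correction turned the sign of 3 named genes, none of them called: Slc2a1 (0.17), Hmgcs1 (-0.10) and Hif1a (-0.33). It ended the calls of 16 named genes, among them Slc40a1 (-0.08, against -0.60) and Mertk (0.08, against 0.56), and leaving out the second APAP library ended 21. Cxcr4 stayed between 1.17 and 1.49. With 1 control library, no alternative shows the control's own spread, and no test was repeated at a lower depth.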

Other observations

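The tests of scaling factors, dilution, cell type share, immunoglobulin and T cell receptor segments, the 5 most abundant B cell genes, library quality, single libraries and other splits were chosen only after the result was seen, and those of olfactory receptor reads and matched lists before. Genes for the uptake of dying cells went both ways. Of 23, 11 were higher and 6 lower, the same over the list alone (camera adjusted p = 0.934). After the length and GC correction 9 were higher and 9 lower. The scavenger receptor Stab1 rose by 2.18 (SE 0.17), the cholesterol exporter Abca1 by 1.51 (SE 0.11; 0.53 after the length and GC correction) and the integrin Itgav by 1.24 (SE 0.11), while the uptake receptor Timd4 and the bridging protein C1qa fell. Of 23 matrix remodelling and growth factor genes, 10 were higher and 3 lower (11 and 3 adjusted over the list alone; camera adjusted p = 0.0757, between 0.000754 and 0.0212 without each APAP library in turn and 0.0421 after the length and GC correction), and 1 was lower without the second APAP library. Thrombospondin (Thbs1) rose from 1.67 to 49.2 ± 17.0 CPM and the membrane metalloprotease Mmp14 by 1.36 (SE 0.20).

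Pattern recognition genes had 12 higher and 6 lower of 27, the same over the list alone (camera adjusted p = 0.367), and 7 and 4 without the second APAP library. After the length and GC correction 8 were higher and 6 lower, with the median at 0.01 against 0.34. Tlr9, a sensor of DNA, rose by 2.22 (SE 0.13) and the fungal receptor Clec7a by 1.21 (SE 0.11), while Ly96, the partner of Tlr4, fell by 1.16 (SE 0.12) and Casp1 by 0.79 (SE 0.09). Immediate early genes, which also respond to tissue dissociation, had 10 higher and 6 lower of 23 (10 and 8 over the list alone; camera adjusted p = 0.492), with Egr1 at 1.97, Egr3 at 4.88, Jund at -1.54 and Klf2 at -1.83, and 8 and 3 without the second APAP library. Of 21 tested myosin genes, picked as a family after the data were seen, 12 were higher and 0 lower, and many of these transcripts are long.

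Most lymphocyte and plasmacytoid dendritic cell markers rose in the APAP libraries: 18 of 18 for B cells, 17 of 20 for T cells, 10 of 16 for NK cells and 9 of 12 for plasmacytoid dendritic cells. Of the NK cell genes 1 fell, and of the plasmacytoid dendritic cell genes 2. Without the second APAP library 11 T cell and 6 NK cell genes rose. The summed CPM of the plasmacytoid dendritic cell list fell short of the control (482, 521 and 547 against 644). Low-level reads over silent genes do not account for a median 11.0-fold rise of the B cell list. Reads on olfactory and vomeronasal receptor genes were 1.73-fold, 1.89-fold and 1.74-fold higher in the APAP libraries than in the control. The 95% interval of the largest ratio was 1.68 to 2.14, for counting error only, without the spread between control libraries. These ratios were set against the B cell list only. They do not settle the smaller median log2 rises of the T cell (1.31) and NK cell (1.56) lists. A lower share of macrophages that raised every other cell type alike would raise the endothelium list as much. The B cell list stood 3.58 above that list in median log2 fold change, which argues against such an even rise only as far as the endothelium list reads endothelial RNA. Of its 21 genes, 20 stood at 1 CPM or more in the control, and whether macrophages supplied some of these reads was not tested. The gap between the lists cannot exclude a lower share of macrophages with more lymphocytes in their place. The number of variable segments with reads grows with the reads on them, so it was compared at equal read numbers. Drawn down to the control's 563 reads, the APAP libraries had reads on 115 to 128 of 244 immunoglobulin heavy and kappa segments against 43, at least 2.67 times as many. At 269 reads they had reads on 63.9 to 70.1 of 132 T cell receptor alpha and beta segments against 30, at least 2.13 times as many. RNA of many B and T cell clones would give this, although reads are not independent molecules. A control library with fewer distinct molecules would also show fewer segments, so the comparison cannot decide. At equal depth the control had reads on 18783 genes, against 23376 to 23776 in the APAP libraries. The smallest rise among the 5 most abundant B cell genes was 1.62-fold, for Cd79b, which decides nothing, since it started at 23.8 CPM in the control against 3.36 for its partner Cd79a, and 17 of 18 members were at least 2-fold higher. The rule for reading this test was changed after its result was seen, since as first written it would have counted against RNA of B cells. Whether such cells passed the Cxcr4+ gate, since lymphocytes also carry Cxcr4, or were bound to or taken up by macrophages stays open. A control gate that held fewer such cells, or the quality of the single control library, cannot be told apart from these.

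Most Kupffer cell identity genes fell, and dilution by cells that lack these transcripts would lower them all by 1 factor. Their log2 fold changes had an SD 3.81 times their median SE (0.79 and 0.21), ranging from -2.46 to 0.62, but that SE holds no spread between control libraries and the length trend could also spread the members, so dilution stays open. Under 3 scaling factors the median stayed at -1.16 or lower. Dilution, recruited cells that express some of these genes and lower expression in resident cells may all contribute, and neither the APAP treatment nor the sort was tested apart from the other.

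Longer transcripts were higher in the APAP libraries, and most oxidative phosphorylation genes, which are short, were lower. The trend over length and GC content that other genes showed does not account for all of the fall of that list. Its median was -0.81, against -0.33 for 10000 random lists matched on transcript length, GC content and expression. The list lay at percentile 0 of these, with 95% of them between -0.56 and -0.05. The matched genes were drawn singly, while the list's members moved together (estimated correlation 0.77), so this percentile does not measure chance. Under the choice of scaling factor the list's median stayed at -0.81 or lower. The length trend held in all 4 quartiles of expression (smallest rho 0.409) and without each APAP library (smallest 0.457), so a single deviating APAP library was not its source. RNA or library quality of the single control library and a difference between the conditions cannot be told apart, because only 1 control library exists.

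The count of called genes has the same limit. Among the 4 splits of the libraries into 3 and 1, 1 gave as many genes, the real one with 8295, and the highest other gave 0 by edgeR, with 138, 39 and 14 genes at an unadjusted p under 0.05. The splits are too few for a share under 0.05. In each other split the control stood in the group of 3 and widened its spread, so few calls were possible there.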
